A study of Drosophila melanogaster with 129 samples.

How the data were processed

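Expression was measured on 129 one-colour oligonucleotide arrays of *Drosophila* S2R+ cells. Per the labels' protocols, all cells received plasmids for GFP under an actin-driven GAL4, some with dsRNA or a further plasmid in addition, and total RNA was made into biotin-labelled antisense RNA. Per the labels, each slide had 4 positions, though some slides lack an array at one of them here. Most slides carried a GFP control, as a rule at the first position, so position and GFP are hard to separate. Groups were taken from the labels, except for 1 array whose title and source name give different genes, which entered no comparison. For the RhoGEF64C RNAi arrays the title was followed, since the source name gives another gene. Replicate numbers were given in accession order and serve as names. Arrays of a group with the same date in their labels were taken as 1 preparation, which gave 17 preparations.

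The deposited spot files hold raw intensity, the median and the mean brightness of the pixels of each of 2240 spots, with no background column and no normalisation, per the file headers and the values. The software that read the images is not given in the sources used here. The authors' deposited value table holds 2072 values per array on a log scale whose base is not stated, with array medians from 6.48 to 6.67. Its rows carry no probe name, so it served for counts alone, as an alternative, on the 1847 rows with a value on every array. The design written before the data were examined assumed values already normalised; the files hold raw intensity, so background correction and normalisation were added.

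The files annotate probes by 2 layouts, used on 43 and 86 arrays. On 8 arrays of 2 slides the intensities followed the layout that their file does not state: their correlation with the other arrays was 0.72 to 0.90 under the layout used and 0.02 to 0.04 under the stated one. These arrays were re-annotated. Probe names give their positions along the transcript, and no genome coordinates were used here.

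The median pixel intensity was corrected with normexp and an offset of 50, put on the log2 scale, averaged over the spots of a probe and quantile normalised over all arrays on the 1847 probes that both layouts share. Of 2072 probes and 1829 genes, 1787 genes had a shared probe. The brightest shared probe stood for the gene, and 54 genes had more than 1. Probes of a gene can disagree, as given for the targeted genes. Of the 1787 genes, 1243 matched a current symbol in the reference, 412 kept a FlyBase number that the reference does not pair with a symbol, 96 kept the name in the file and 36 had several names. Up to 22 spots per array were saturated, on 72 arrays, and were kept. For values at layout-specific probes, each layout was normalised by itself.

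All 128 grouped arrays entered 1 linear model in limma 3.58.1 (R 4.3.3, statmod 1.5.0, with data.table version 1.17.8), with group and slide as fixed effects and preparation within group as a random effect through duplicateCorrelation (consensus correlation -0.00487, 45 residual and 10.7 prior degrees of freedom). Arrays of a slide deviated from their group means together, with a median r of 0.56 over 129 pairs against -0.02 between slides. Moderated tests were 2-sided, with Benjamini-Hochberg adjustment over the 1787 genes of each comparison and a threshold of 0.05. Adjusted p-values in the text are from this fit unless they are named otherwise. For targeted genes a second adjustment ran over the 17 target tests alone. Groups of 1 array or of 1 preparation were given as the log2 ratio to the GFP array of the slide, with no p. No arrays held identical values; the median correlation within a group was 0.76.

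Gene lists were fixed before the data were examined: 26 lists, of which 11 had the minimum of 5 measured members. They were tested with camera at a preset correlation of 0.01, adjusted over 220 tests, and again with an estimated correlation. The RhoGAP list holds the symbol rn, which the reference gives to the transcription factor rotund. The comparisons, the tests, the lists and the rule for named genes were all set before the data were examined. The rule took the targeted gene, then genes past the threshold with the same sign against the slide GFP on every array, up to 8 each way by size (largest log2 fold change) for the Rho1, Rac1, Cdc42 and average RNAi comparisons and up to 4 each way in the others. For average RNAi the sign had to hold in at least 80% of arrays, and for a pair of RNAi groups every array of the first had to lie on the same side of the mean of the second; this form of the rule for pairs was added with the code. It also took up to 3 members by smallest p of each list described in those comparisons and up to 2 in the others, and, where no gene passed, the 4 genes with the smallest p. Which lists to describe was decided after the list results were seen. Genes without a symbol were left out of the text where they exceeded 2 higher and 2 lower ones.

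Similarity of responses was Pearson's r across genes, set beside 100 simulations of unchanged groups in the same design, and computed again with the GFP arrays split into 15 and 15. For shared calls, the simulations took as many genes by the largest moderated t as were called in each comparison and counted those shared with the same sign. The fit was tested on simulated data with 200 changed genes of 1787. Of those changed 2-fold, 94% were recovered for the Rho1 RNAi design, 95% for Rac1, 74% for Cdc42, 85% for Mtl and 84% for CG3799. For the other designs it was between 49% (RhoGEF4) and 90% (RhoBTB). False calls made up at most 8.2% of calls (RacF28L). The simulated noise was independent between genes, with the same spread on every array, while quality weights of the real arrays ran from 0.0151 to 13.58. With 200 planted changes the adjusted threshold is also easier to pass than where few genes change. These shares are thus not the power of the real comparisons. Alternatives covered the background, the spot value, the normalisation, a filter on dim genes, the slide, preparation and position effects, the reference, the fold minimum, the moderation, array weights and each array left out; the closing section gives their effect. Values at single probes and per amplicon have no test unless one is given.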

Results

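Expression of genes was measured on 129 one-colour oligonucleotide arrays hybridised with RNA from S2R+ cells, an adherent line of *Drosophila melanogaster* derived from late embryos. The cells had been transfected with plasmids that express green fluorescent protein (GFP) under the GAL4 system, and in addition with double-stranded RNA (dsRNA) against a gene of the Rho family network or with a plasmid that encodes such a protein. Rho GTPases are molecular switches that shape the actin cytoskeleton; guanine nucleotide exchange factors (GEFs) turn them on and GTPase activating proteins (GAPs) turn them off. Of the 128 arrays with a group, 30 came from cells that received GFP alone, 80 fell into 36 RNAi groups and 18 into 14 plasmid groups. A single array stood for 25 of these 50 groups. The arrays lay on 33 slides of 4 positions, and 3 slides held no GFP array. The median spot intensity per array ran from 111 to 4364.2, and 1787 genes could be compared on all arrays. The number of arrays per group limits the precision of each comparison. The labels do not say whether arrays of a group came from separate cultures, so the p-values measure the spread between arrays, part of which may be technical. Each n counts arrays. By date they came from 3 preparations for Rho1 RNAi, 4 for Rac1 and 2 for Cdc42, Mtl, RhoBTB, RhoGAP1A and CG3799. Within a group the median r was 0.87 in a preparation and 0.75 between preparations. With a consensus correlation of -0.00487, arrays of 1 preparation in effect counted as independent.

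In each RNAi group the targeted gene was examined first, as a check of the labels. Rho1, the GTPase that activates actomyosin contraction, was lower under Rho1 dsRNA by a log2 fold change of -2.43 ± 0.21 (SE, n = 5 arrays, adjusted p = 2.11e-13), and lower than the GFP array of the same slide on 5 of 5 arrays. Rac1, the GTPase linked to lamellipodia, was lower under Rac1 dsRNA by -2.02 ± 0.42 (n = 8 arrays, adjusted p = 0.0226), on 6 of the 6 arrays that had a GFP array on their slide. In the single array with both dsRNAs, Rac1 lay at a log2 ratio of -2.43 and Rho1 at -2.22 to the GFP array of the slide. Over the 17 tests of targeted genes alone, 6 passed: 4 RNAi targets were lower, 1 was higher (Mtl), and sif was lower with its full-length plasmid. Among them RhoGAPp190, a GAP for Rho, was lower in its RNAi group (-0.79 ± 0.30, n = 2, adjusted p = 0.0332 over the targets alone; -0.22 at 6316 to 6350, and a mean ratio of 0.52 at 7012 to 7046), as was the exchange factor RhoGEF4 (-0.74 ± 0.23, n = 2, adjusted p = 0.00790 over the targets alone). Both missed the threshold over all genes. Of the 36 RNAi ratios of a target gene to the GFP array of the slide, 22 were below 0, 4 were below -1 and 3 were above 1. RhoL was not lower in the arrays labelled RhoL RNAi (n = 3), with mean ratios of 0.05, 0.01 and 0.05 at its 3 probes.

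Probes of a gene differed in what they read. Cdc42, the GTPase tied to filopodia and polarity, had a log2 fold change of only -0.40 ± 0.21 under its dsRNA (n = 5, adjusted p = 0.438) at the brightest probe, at transcript positions 802 to 836. The probe at 914 to 948 gave -3.51 (adjusted p = 2.52e-23 over all probes), and the probe at 752 to 786, present on the second array layout, gave a mean ratio of -5.14 with a range of -5.51 to -4.64 over 5 arrays. The GAP tum, a centralspindlin subunit also called RacGAP50C, differed less between probes: -0.10 at the probe that stands for the gene in the 2 RhoGAP50C RNAi arrays and -1.43 at 1789 to 1823, and -0.78 and -1.11 at these probes in the RacGAP50C RNAi array. In other groups a probe was higher in the arrays labelled for dsRNA against its own gene. Mtl, a Rac-like GTPase, was higher by 2.26 ± 0.21 in the arrays labelled Mtl RNAi (n = 3, adjusted p = 1.36e-11, 3 of 3 arrays) at 574 to 608, while the probe at 958 to 992 read -0.43 (adjusted p = 0.705 over all probes). In the arrays labelled RhoGEF4 RNAi the probe at 1305 to 1339 gave 5.08 (n = 2, adjusted p = 2.40e-21 over all probes) and the probe at 1985 to 2019 gave -0.74; with all probes averaged the RhoGEF4 value was 1.36. In the array labelled Cdep RNAi a probe of Cdep, a FERM-domain exchange factor, had a ratio of 6.72, and in the array labelled CG30456 RNAi a probe of CG30456 had 2.42. The probes that do not stand for their gene were singled out after their values were seen.

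**Figure D1:**
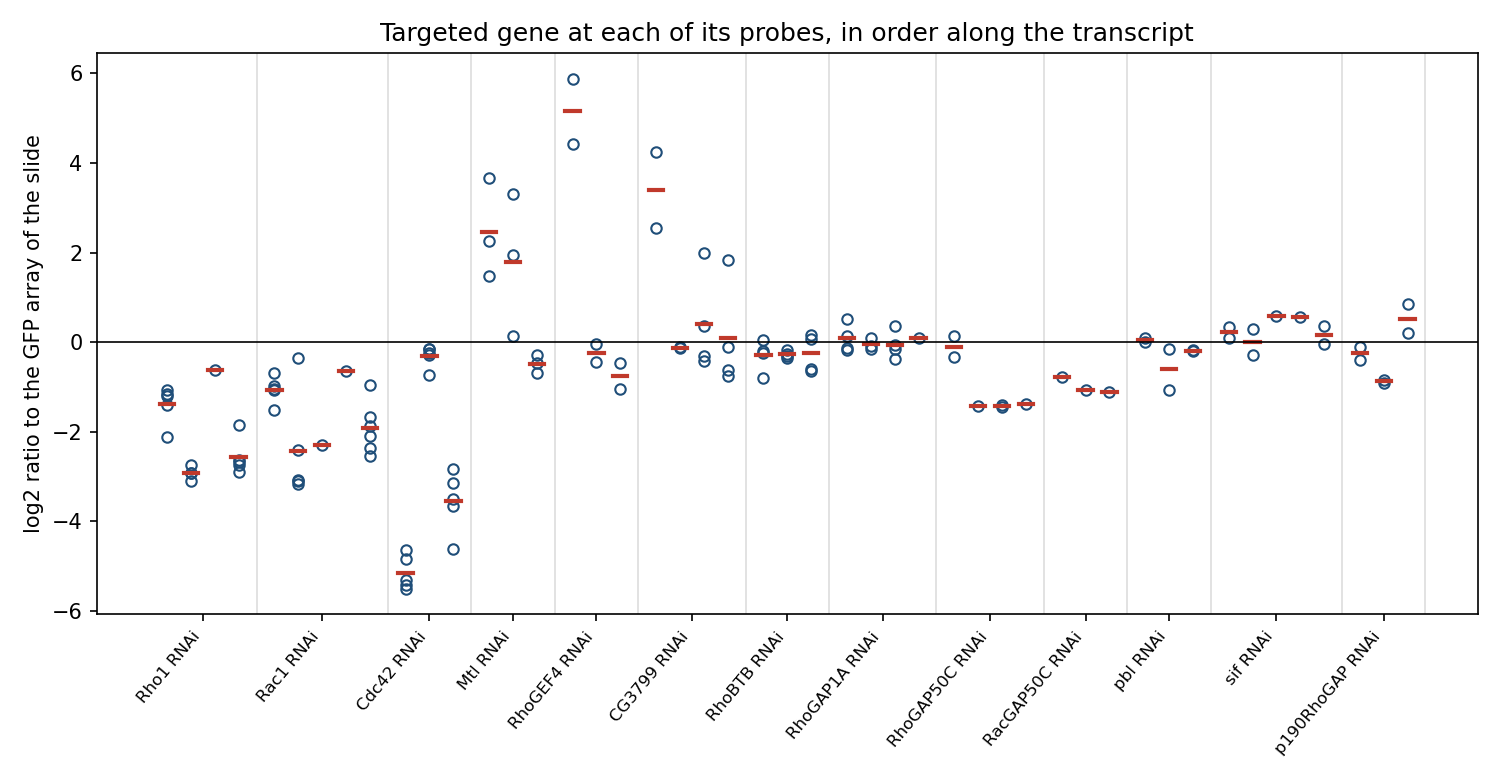
Log2 ratio of the targeted gene to the GFP array of the same slide (vertical axis) for 13 RNAi groups (horizontal axis), with the probes of each gene in order along the transcript. Circles are single arrays and red bars are means; Cdc42 has means of -5.14, -0.31 and -3.54 at its 3 probes, and RhoGEF4 has 5.16, -0.24 and -0.75.

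The labels of some Rac1 RNAi arrays name the stretch amplified for the dsRNA: amplicon 1, which covers Rac1 and Rac2, or amplicon 2, which covers Rac1 alone. At the probe at 1414 to 1448, the ratio of Rac1 to the GFP array of the slide was -0.90 in the 1 amplicon 1 array with such a control, -1.55 in the 1 amplicon 2 array, and had a mean of -2.24 (range -2.46 to -1.78) in the 4 arrays whose amplicon is not stated. The GFP array of the amplicon arrays was itself low at this probe (10.64 in normalised log2 intensity, against a median of 12.07 over the GFP arrays of this layout). The Rac1 levels were 9.69 and 8.98 with amplicons 1 and 2 and 10.31 to 10.55 in the 3 arrays of this layout with no amplicon stated, so levels and ratios rank the arrays differently. Rac2, a close relative of Rac1 with overlapping function, had ratios of 0.12 and 0.12 with amplicons 1 and 2, which centring on the median moved to 0.30 and 0.42. In Rac2 RNAi, Rac2 had a log2 fold change of -0.30 ± 0.24 (n = 2, adjusted p = 0.333 over the targets alone), and the probe at 634 to 668 had a ratio of -0.85 on 1 array. The amplicons differed by probe: the amplicon 1 array had ratios of -1.07, -2.41 and -0.95 at 906 to 940, 988 to 1022 and 1414 to 1448, and the amplicon 2 array had -1.52, -0.36 and -1.66. A second array of each amplicon, on a slide without GFP, repeated the difference in levels: at 988 to 1022 amplicon 1 read 9.03 and 9.07, and amplicon 2 read 11.07 and 11.37.

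**Figure D2:**
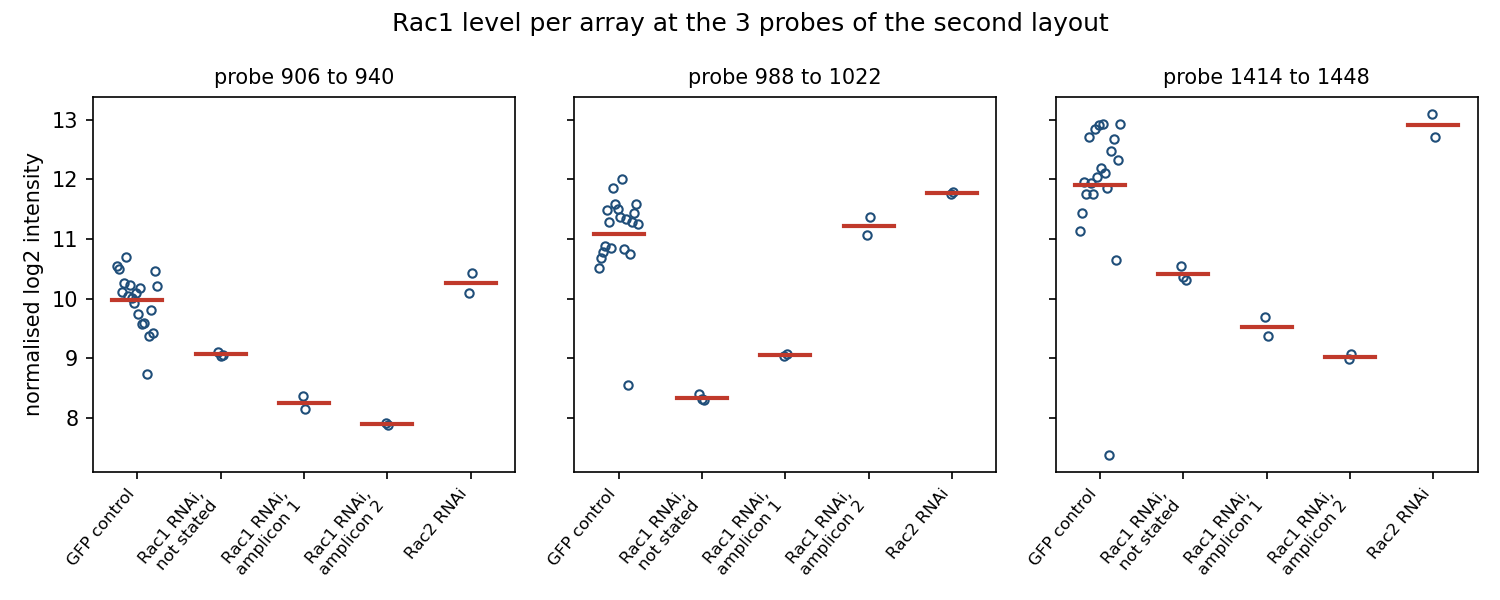
Normalised log2 intensity of Rac1 (vertical axis) on each array at 3 probes of the second layout (panels), for GFP, for Rac1 RNAi by amplicon and for Rac2 RNAi (horizontal axis). At 988 to 1022 the amplicon 2 array with a GFP control lies at a ratio of -0.36 to it, and the amplicon 1 array at -2.41.

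Rho1 RNAi was compared with GFP to find genes that respond to loss of Rho1. Beside Rho1 itself, FBgn0024290, which has no symbol here, was higher by 1.18 ± 0.22 (SE, n = 5, adjusted p = 0.00108, 5 of 5 arrays) and FBgn0027569 was lower by -0.52 ± 0.12 (adjusted p = 0.0489, 5 of 5 arrays). These 3 genes, 1 higher and 2 lower, were the ones past adjusted p 0.05 in limma, and 150 genes had an unadjusted p under 0.05. Without any change, a share of about 0.05 of the 1787 genes would have such a p. Over the comparisons with GFP this count ran from 2 (RhoGEF4 RNAi) to 302 (full-length Sif plasmid), on both sides of that share. It is thus not read as a sign of response. For genes named past the threshold, the same sign on every array was a condition of the rule. In Rho1 RNAi against GFP, array quality weights gave 303 genes and no background correction gave 5, while 1 gene passed with no slide in the model, with median centring, with the authors' table, with preparation ratios and with only the compared groups. FBgn0027569 lost the threshold in 13 of 21 settings and FBgn0024290 in 5. Among 36 genes of the actin cytoskeleton and actomyosin, 20 had values above 0 and 0 passed, either over all genes or adjusted over the list alone (camera, adjusted p = 0.921). The formin dia, which elongates unbranched filaments downstream of Rho, had the smallest p of that list (0.60 ± 0.19, adjusted p = 0.325, 5 of 5 arrays; -0.22 without slide in the model). The cofilin tsr, which severs filaments, had -0.35 ± 0.21 and vinculin (Vinc) 0.22 ± 0.17. Of 13 cytokinesis genes, 8 had values above 0; Rho1 passed over all genes, Rho1 and dia passed adjusted over the list alone, and pav, the kinesin of centralspindlin, had 0.37 ± 0.19 (-0.13 without slide in the model). The mean of this list was -0.12, its median 0.01 and its direction in camera down (adjusted p = 0.908). Of the 7 Rho GTPases, Rho1 passed in both counts and 4 had values above 0, among them Cdc42 (0.19 ± 0.17; -0.03 with arrays centred on the median) and Rac1 (0.41 ± 0.43); the mean was -0.27, the median 0.02 and the camera direction down (adjusted p = 0.393).

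The same question was asked of Rac1. Tomosyn, an inhibitor of vesicle fusion, was higher under Rac1 RNAi by 1.14 ± 0.26 (n = 8, adjusted p = 0.0493, 6 of 6 arrays), and FBgn0024290 was higher by 0.91 ± 0.21 (adjusted p = 0.0493, 6 of 6 arrays). With Rac1 these were the 3 genes past the threshold, 2 higher and 1 lower; 100 had an unadjusted p under 0.05. Rho1 had a value of -0.56 ± 0.20 (adjusted p = 0.575, 6 of 6 arrays), and was past the threshold with Rac1 when the 7 Rho GTPases were adjusted over the list alone (2 of 7, 4 with values above 0). Replicate 1 had a Rho1 ratio of -1.76, against -0.61 to -0.13 in the other 5 arrays; the value was -0.36 without it (adjusted p = 0.979) and -0.17 without slide in the model. That list had a mean of -0.33 and a median of 0.04 (camera direction down, adjusted p = 0.510), and Cdc42 lay at 0.19 ± 0.17 (-0.10 without slide in the model). Of the 36 actin genes 19 had values above 0 and 0 passed in either count (camera, adjusted p = 0.921); rhea, which encodes talin, had 0.86 ± 0.34 (adjusted p = 0.749), dia 0.47 ± 0.19 and the formin capu -0.42 ± 0.21. Of the 13 cytokinesis genes 5 had values above 0 and 0 passed in either count (mean 0.01, median -0.05, camera direction up, adjusted p = 0.983), with pav at 0.51 ± 0.19 (0.32 without replicate 1, where its ratio was 1.34 against 0.11 to 0.46). The count of 3 fell to 0 without Rac1 RNAi replicate 1 or 4 or GFP replicate 20 or 21, and to 1 without Rac1 RNAi replicate 5, 6 or 8 or GFP replicate 28. It was 1 with the position on the slide in the model and 215 with array quality weights.

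Under Cdc42 RNAi, eEF5, a translation elongation factor, was higher by 2.27 ± 0.43 (n = 5, adjusted p = 0.00155, 5 of 5 arrays). Arp2, a subunit of the Arp2/3 complex that nucleates branched actin, was lower by -1.23 ± 0.21 (adjusted p = 4.06e-04, 5 of 5 arrays), and PolE4, a histone-fold subunit of DNA polymerase epsilon, by -1.41 ± 0.31 (adjusted p = 0.0201, 5 of 5 arrays; 0.05 without slide in the model). These 3 genes, 1 higher and 2 lower, passed, and 219 had an unadjusted p under 0.05. Of 36 actin genes 13 had values above 0, Arp2 passed over all genes and 3 passed adjusted over the list alone (camera, adjusted p = 0.326); the membrane linker Moe had -1.29 ± 0.37 (adjusted p = 0.0915) and capu -0.85 ± 0.26. Of 13 cytokinesis genes 3 had values above 0 and 3 passed adjusted over the list alone: Rho1 (-0.94 ± 0.25, adjusted p = 0.0869 over all genes), tum (-0.77 ± 0.23) and tsr (-0.71 ± 0.25). Of the 7 Rho GTPases 1 had a value above 0, and Rho1 and RhoL (-0.86 ± 0.28) passed adjusted over the list alone, while Rac2 had -0.37 ± 0.19. Without the 3 arrays that agree least with the others, 2 actin genes, 1 cytokinesis gene and 0 Rho GTPases passed adjusted over their list, and 19, 6 and 0 had values above 0; RhoL and Moe lay at -2.42 and -3.27 in replicate 5, against -0.41 to -0.14 and -0.82 to -0.06 in the other 4. The cytokinesis and Rho GTPase lists missed the threshold in camera (adjusted p = 0.0794 each, and adjusted p = 0.766 each with an estimated correlation). Both passed with no background correction (camera, adjusted p = 0.045 each). Cytokinesis also passed with the mean of the other RNAi groups as the reference (camera, adjusted p = 0.0477). The count of 3 was 220 without Cdc42 RNAi replicate 4, 86 without GFP replicate 18 and 0 without GFP replicate 19. Of these 3 genes, 1 stayed past the threshold with no slide in the model. The count also moved widely with the slide effect and the normalisation, as the closing section gives. The 5 arrays lay on 2 slides, and replicate 5 had a correlation of 0.43 with the mean of all other arrays. These arrays were dim: median spot intensities were 131 to 160.5, and 111 and 143 on their GFP arrays, in a series that reached 4364.2. Their labels give G8 for 3 arrays and D21 for 2, taken here as dsRNA reagents and pooled.

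The GTPase knockdowns were then set against each other in the same fit. Rac1 and Cdc42 RNAi shared no slide, and Rho1 and Cdc42 RNAi met only on the slide of Rho1 RNAi replicate 2. With slide in the model, the contrasts with Cdc42 RNAi thus run mainly through GFP arrays. They partly restate Cdc42 RNAi against GFP, where Arp2 and PolE4 were already lower. Between Rho1 and Rac1 RNAi, Rho1 (-1.87 ± 0.22, adjusted p = 1.97e-08) and Rac1 (2.44 ± 0.45, adjusted p = 0.00134) differed, and 2 genes passed in all; 71 had an unadjusted p under 0.05. Between Rho1 and Cdc42 RNAi, 16 genes passed, 15 higher with Rho1 RNAi and 1 lower, with 244 at an unadjusted p under 0.05. Rho1 was lower (-1.49 ± 0.29, adjusted p = 0.00267). CG32625 (1.86 ± 0.38, adjusted p = 0.00357) and Sema2a, a secreted guidance cue (1.65 ± 0.32, adjusted p = 0.00267), were higher with Rho1 RNAi. So were, chosen after their values were seen, Arp2 (1.40 ± 0.24), the trafficking GTPase Rab8 (1.40 ± 0.36) and tum (0.98 ± 0.26). Between Rac1 and Cdc42 RNAi the 2 genes past the threshold were PolE4 (1.83 ± 0.38, adjusted p = 0.0108; -0.10 without slide in the model) and Arp2 (1.34 ± 0.25, adjusted p = 0.00400), both higher with Rac1 RNAi; 215 had an unadjusted p under 0.05, tum stood at 0.76 ± 0.28 and pav at 0.71 ± 0.28. The 16 genes became 273, 10 and 2 without Cdc42 RNAi replicates 4, 3 and 5, 2 without Rho1 RNAi replicate 2, 80, 8, 9 and 10 without GFP replicates 18, 19, 20 and 21, and 8 with position in the model. The 2 genes of the last comparison became 190 and 0 without Cdc42 RNAi replicates 4 and 5, and 47 and 7 without GFP replicates 18 and 28.

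In the arrays labelled Mtl RNAi, 2 genes passed, both higher: Mtl, as given above, and FBgn0028484 (2.48 ± 0.55, adjusted p = 0.0268). FBgn0028484 did not keep its sign on every array, so it lay outside the rule for named genes. It was chosen after its values were seen, and lost the threshold in 9 of 19 settings. An unadjusted p under 0.05 was found for 78 genes. The 5 measured genes of the JNK pathway all had values above 0 and 1 passed adjusted over the list alone (camera, adjusted p = 0.143): the ETS factor Ets21C had 0.58 ± 0.20 (adjusted p = 0.695, 3 of 3 arrays) and the homeobox gene mirr 0.34 ± 0.22. Of the 7 Rho GTPases 3 had values above 0, with Mtl past in both counts and RhoBTB at 0.27 ± 0.19 (-0.29 without slide in the model); the mean was 0.28, the median -0.02 and the camera direction up (adjusted p = 0.144). The count of 2 became 6, 1 and 7 without Mtl RNAi replicates 1, 2 and 3, 1 without GFP replicate 25, and 1 with position in the model.

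RhoBTB is an atypical Rho-family protein with BTB domains. In RhoBTB RNAi, RhoBTB had a value of -0.19 ± 0.17 (n = 4, 4 of 4 arrays below the GFP array) and 0 genes passed in limma, with 24 at an unadjusted p under 0.05. The 4 genes with the smallest p were e(y)2, a subunit of the SAGA and mRNA export complexes (-0.67 ± 0.19), Rac1 (-1.20 ± 0.45), the tubulin betaTub60D (-0.73 ± 0.28) and twy (0.46 ± 0.19); adjusted p was 1.00 for each. The Rac1 value rests on the array labelled RhoBTB RNAi replicate 4, at a ratio of -3.98, while the other 3 lay between -0.74 and -0.09. Of 36 actin genes, 12 had values above 0 and 0 passed in either count (camera, adjusted p = 0.125, and adjusted p = 0.766 with an estimated correlation); Act87E had 0.48 ± 0.23 (-0.19 without slide in the model) and WASp -0.37 ± 0.18, with an adjusted p of 1.00 for each. In RhoGAP1A RNAi, RhoGAP1A had 0.09 ± 0.18 (n = 4, and -0.05 without replicate 4) and 0 genes passed in limma, with 61 at an unadjusted p under 0.05. The scaffold of JNK signalling POSH had 0.56 ± 0.18 and CG8152 0.67 ± 0.21, on 4 of 4 arrays each (adjusted p = 0.997). The authors' table and array quality weights raised the RhoGAP1A count, as the closing section gives.

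CG3799, listed in the reference as Exn, is the fly ephexin, an exchange factor. In the arrays labelled CG3799 RNAi, Exn had 0.20 ± 0.30 (n = 4, adjusted p = 0.846), with a ratio of 1.84 in replicate 2, against its label, and -0.72 to -0.11 in the other 3. Without replicate 2 the value was -0.51. At 2970 to 3006, a probe of the first layout, replicates 1 and 2 had ratios of 2.56 and 4.235, both against the label. Vinculin (Vinc), which links integrin adhesions to actin, was higher by 0.72 ± 0.18 (adjusted p = 0.0330), as were antr (1.00 ± 0.22), the chromatin factor d4 (0.91 ± 0.19, adjusted p = 0.0191) and CG32280 (0.74 ± 0.18). Klp64D, a motor subunit of kinesin-2, was lower by -1.01 ± 0.23 (adjusted p = 0.0330), as was Orf5C (-1.25 ± 0.31). Each of these held its direction on 4 of 4 arrays, a condition of being named that the remaining lower gene failed. In all 9 genes passed, 6 higher and 3 lower, and 218 had an unadjusted p under 0.05. The count became 2 without CG3799 RNAi replicate 3, and 0, 2 and 37 without GFP replicates 2, 25 and 26. It was 1 with position in the model.

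Still life (sif) is an exchange factor for Rac. In the arrays labelled sif RNAi, sif was not lower (0.34 ± 0.25, n = 4, adjusted p = 0.707). There 0 genes passed in limma, although 174 had an unadjusted p under 0.05. The 4 smallest p belonged to Lsp1gamma, a larval storage protein (-1.47 ± 0.33), CG7083 (1.19 ± 0.27), CG42450 (1.16 ± 0.27; adjusted p = 0.0503 for each of these 3) and the nuclear receptor Hr96 (0.96 ± 0.24, adjusted p = 0.0623). Of 4 arrays, 2 had a GFP array on their slide, and both showed these directions. The count was 20 without sif RNAi replicate 2, 2 without replicate 3 and 1 without GFP replicate 8.

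Pebble (pbl) is the exchange factor that activates Rho1 at the cleavage furrow, and RacGAP50C (tum) its partner there. In pbl RNAi, pbl had -0.41 ± 0.26 (n = 3) and 0 genes passed in limma, with 33 at an unadjusted p under 0.05; the proneural factor ase had -0.87 ± 0.26, CG7246 0.71 ± 0.23 and the odorant-binding protein Obp69a 1.04 ± 0.35 (adjusted p = 1.00 each; Obp69a -0.18 without slide in the model). In the 4 arrays labelled RhoGAP50C or RacGAP50C RNAi, tum had -0.42 ± 0.21 (adjusted p = 0.607, and 0.120 over the targets alone) and 0 genes passed in limma, with 146 at an unadjusted p under 0.05. There CG34347 had -0.76 ± 0.20, Arv1, which acts in sterol transport, -0.69 ± 0.20, CG32247 0.78 ± 0.23 and the zinc finger factor opa 0.93 ± 0.28 (adjusted p = 0.354 each). That count was 4 without RhoGAP50C RNAi replicate 2, 1 without RacGAP50C RNAi replicate 1, and 1 and 5 without GFP replicates 9 and 11. For pbl it was 1 when 1 array was left out. Array quality weights and the authors' table raised the pbl count further, as the closing section gives.

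In the RhoGAPp190 arrays (labelled p190RhoGAP RNAi, n = 2) and the arrays labelled RhoGEF4 RNAi (n = 2), 0 genes passed in limma. Fewer genes than the share for unchanged genes had an unadjusted p under 0.05, 6 in the RhoGAPp190 arrays and 2 in the RhoGEF4 arrays. In the former, RhoGAPp190 and Rab3-GAP, a regulator of Rab GTPases in membrane traffic (-0.91 ± 0.38), were followed by CG32590 (-0.65 ± 0.29). In the latter, RhoGEF4 was followed by bin, a FoxF factor of visceral muscle (-0.68 ± 0.36; 0.23 without slide in the model), and CG31279 (-0.56 ± 0.33). Adjusted p was 1.00 for each over all genes.

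Plasmids for GTPases were the counterpart of the knockdowns. In the single arrays with RhoV14 and RacV12, Rho1 read 14.87 and Rac1 14.50 in normalised log2 intensity, above the highest values of the arrays that neither targeted nor carried the gene, 12.15 and 12.70. The other Rho1 probe of the joint fit, at 212 to 248, read 10.18 with RhoV14, inside the range of those arrays (7.24 to 11.67). The slide of both held no GFP array. The RacF28L and RhoF30L plasmids (n = 2 each) left the probes of their gene near the GFP level, with Rac1 at -0.41 ± 0.67 and Rho1 at -0.09 ± 0.33. In both, 0 genes passed in limma, with 12 and 46 at an unadjusted p under 0.05. CG1785 had -0.95 ± 0.35 with RacF28L and -1.11 ± 0.35 with RhoF30L, and CG30010 -0.83 ± 0.34 and -0.88 ± 0.34; e(y)2 had -0.68 ± 0.29 with RacF28L and the dynein light chain Cdlc2 0.77 ± 0.27 with RhoF30L. Of 36 actin genes, 10 had values above 0 with RhoF30L and 0 passed in either count; the cytoplasmic actins Act42A and Act5C had -1.27 ± 0.50 and -0.75 ± 0.35 (camera, adjusted p = 0.0794, and adjusted p = 0.766 with an estimated correlation). With RacF28L, Act42A had -0.89 ± 0.50 and Act5C -0.62 ± 0.35. Act5C was lower than the GFP array of the slide on 1 of 2 arrays for each plasmid. Both plasmids lay on the same 2 slides and were set against the same GFP arrays. Values that they share thus cannot be told apart from those controls.

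Single arrays with further plasmids gave target values without a replicate. In the truncated RhoGEF64C array RhoGEF64C had a ratio of 6.52, and Exn had 0.81 in the truncated and 2.60 in the full-length CG3799 array at 3609 to 3643, but 4.82 and 3.58 at 3317 to 3351. RhoGEF3 was not raised: it had 0.17 and -0.84 at 2 probes in the truncated and -0.09 and -1.08 in the other RhoGEF3 array. RhoGAP1A had 0.07 with its plasmid at the probe that stands for it and 1.16 at 3028 to 3062, and Cdc42 had -0.13 with Cdc42Y32A. In the truncated Pbl array the pbl probes at 4632 to 4666, 4680 to 4714 and 4828 to 4862 had ratios of 1.23, -1.24 and 0.87 in the first layout.

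In the arrays labelled full-length Sif plasmid, 39 genes passed, 16 higher and 23 lower, with 302 at an unadjusted p under 0.05. Rab26, a GTPase of secretory vesicles, was lower by -1.87 ± 0.32 (n = 2, adjusted p = 4.31e-04), CG32453 by -1.87 ± 0.33 (adjusted p = 4.31e-04), the transcription factor lilli by -1.83 ± 0.52 (adjusted p = 0.0453) and FBgn0004864 by -2.72 ± 0.79 (adjusted p = 0.0480). Ir94a, an ionotropic receptor, was higher by 1.54 ± 0.33 (adjusted p = 0.0117) and CG32121 by 1.18 ± 0.30 (adjusted p = 0.0254). The sif gene was lower by -0.95 ± 0.27 (adjusted p = 0.0434), against the label, at the probe that stands for the gene, where the arrays read -1.63 and -0.29; the other 2 shared probes gave -0.04 and -0.45 (adjusted p = 0.962 and 0.384 over all probes). With the truncated form 18 genes passed, 6 higher and 12 lower, with 245 at an unadjusted p under 0.05; Ets21C was higher by 0.98 ± 0.24 (n = 2, adjusted p = 0.0356) and CG31174 by 0.95 ± 0.25, while the RNA gene CR31032 (-1.42 ± 0.37, adjusted p = 0.0417) and the alkaline phosphatase Alp11 (-1.33 ± 0.34) were lower, and sif had -0.31 ± 0.27. Each gene held its direction on 2 of 2 arrays, which the rule required of the genes named past the threshold. Of the genes past in both, 6 had the same sign. Chosen after their values were seen, these include Ets21C, CR31032, Alp11 and eIF4E5, a cap-binding protein. Of the 39 genes, 2 stayed past the threshold with array quality weights and 0 with no slide in the model. Of the 18 genes, 0 stayed past it in either setting. The 39 genes became 107 and 0 without replicates 1 and 2 of the group and 59 and 13 without GFP replicates 2 and 8; the 18 became 0 without replicate 2, 30 and 0 without GFP replicates 2 and 8, and 0 with position in the model.

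The average of all RNAi groups was compared with GFP to find genes that respond to dsRNA as such. CG9876 (-0.38 ± 0.08, adjusted p = 0.0463) and CG34347 (-0.32 ± 0.07, adjusted p = 0.0491) were lower in the average, with 80 RNAi arrays. Neither kept its sign in 80% of the arrays with a GFP array on their slide. Both thus lay outside the rule for named genes and were chosen after their values were seen. CG9876 lost the threshold in 8 of 13 settings and CG34347 in 11 of 14. These 2 genes passed, and 109 had an unadjusted p under 0.05. With position in the model, 0 passed in limma.

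Over 11 gene lists and 20 comparisons, 0 of 220 camera tests passed with the preset correlation and 0 with an estimated one. The smallest adjusted p of a list not yet given was 0.326 for fat body and epithelial markers, where 0 of 6 genes had values above 0 under Rac1 RNAi, and 0.393 for muscle markers, where 1 of 7 did with truncated Sif and paramyosin (Prm, chosen after its values were seen) was lower by -1.08 ± 0.29. It was 0.503 for the RhoGAPs (13 of 19 above 0, Rho1 against Cdc42 RNAi), 0.503 for antimicrobial peptides and other immune targets (11 of 15 above 0, Rho1 against Rac1 RNAi), 0.625 for the ecdysone response (6 of 9 above 0, RhoF30L), 0.754 for apoptosis (5 of 6 above 0, RhoGAP1A RNAi) and 0.765 for the RhoGEFs (12 of 18 above 0, Mtl RNAi).

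Responses were also compared across genes, which are not independent replicates, by Pearson's r between log2 fold changes over 1787 genes. Because comparisons share GFP arrays, unchanged groups were simulated in the same design. The simulated noise was independent between genes and had the same spread on every array. Quality weights of the real arrays ran from 0.0151 to 13.58. The simulated range may thus be too narrow, and a value outside it does not exclude chance. Rho1 and Rac1 RNAi gave r = 0.60 against a simulated 0.43, and 0.19 with split controls; their covariance exceeded the simulated one by 0.0160, and they shared 1 call, FBgn0024290. Independent lists would share 0.00224, but as many top genes of unchanged groups with the same GFP arrays shared 1 in 16 of 100 simulations. Truncated and full-length Sif gave 0.62 against 0.40, and 0.28 with split controls, with a covariance difference of 0.0722 and 6 shared calls; independent lists would share 0.208, and as many top genes of unchanged groups shared a mean of 2.17 and at most 5. Rho1 with Cdc42 (0.10 against 0.24), Rac1 with Cdc42 (0.02 against 0.10) and pbl with RhoGAP50C and RacGAP50C (0.14 against 0.36) lay below the simulated value. Without the 3 arrays that agree least with the others, the first 2 turned to 0.41 and 0.36, above the 0.18 and 0.08 of unchanged groups in that design, and with position in the model the last turned to 0.50, above 0.43. The r of sif RNAi with truncated Sif was 0.25, at the simulated 0.25. The others were Rho1 with pbl RNAi (-0.18), Rho1 with RhoGAP50C and RacGAP50C (0.05), Rho1 RNAi with RhoF30L (-0.03), Rac1 RNAi with RacF28L (-0.00119) and truncated Sif with RacF28L (-0.04), where simulated values were about 0. With position in the model the negative values turned to 0.21, 0.30, 0.27 and 0.26, of Rho1 with pbl, Rho1 with RhoF30L, Rac1 with RacF28L and truncated Sif with RacF28L, where unchanged groups gave 0.09, 0.14, 0.20 and 0.19.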

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

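The tests of the patterns below and of other splits of the arrays were all chosen after the results were seen. Among 49 groups of values examined for an array far from its group, 7 were found. Chance would give about 2.45 if the values were normal and independent. They were not independent, since several of the 7 came from Cdc42 RNAi replicate 5 or Rac1 RNAi replicate 1. No conclusion is drawn from that number.

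Probes of 5 genes were higher in the arrays labelled for their own dsRNA: Exn (CG3799), Mtl, CG30456, Cdep and RhoGEF4. The tables argue against a rise of the whole transcript on 8 of the 9 arrays that have the probe, where the lowest probe of the gene had a ratio of at most 0.213; in CG3799 RNAi replicate 2 all 3 Exn probes were raised, the lowest by 1.84, and such a rise stays open there. A wrong label stays open: in groups with at least 2 arrays that have the probe and a rise on at least 1, 8 of 9 arrays showed it, the exception being RhoGEF64C RNAi, and Cdep and CG30456 have 1 array each. That probes read the dsRNA itself is a candidate explanation that cannot be told either: the raised probe lay at least 1.93 above the lowest on each array, but this restates what was seen, and the stretch each dsRNA covers is not in the labels. No biological explanation was tested.

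Rac1 was low in the array labelled RhoBTB RNAi replicate 4, at -3.98 where the other 3 lay between -0.74 and -0.09, and in the array labelled RhoL RNAi replicate 3 on the same slide, at -3.37. Among 100 genes of like level, 0 lay as low as Rac1 on either array. Their median moved the other way, by -0.0339 and -0.0370 of the Rac1 change. Quantile normalisation holds such a median near 0, so these values cannot decide on an array-wide loss of signal. Before normalisation the median spot intensities were 950 and 647, and 1295 on the GFP array of the slide. An effect of RhoBTB or RhoL dsRNA is argued against by the other 5 arrays of these groups, the lowest of which lay at -0.74. The values at 3 Rac1 probes came within 0.394 of the mean of the nearer amplicon of Rac1 dsRNA, amplicon 2 for the first array and amplicon 1 for the second. At 906 to 940 the arrays read 7.51 and 7.94, below all GFP arrays of the layout (8.74 to 10.7). At 988 to 1022 and 1414 to 1448 both lay inside the GFP range (8.55 to 12.01 and 7.39 to 12.93). A wrong label may account for both arrays. Each amplicon is known from few arrays, and this stays a hypothesis.

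The Sif plasmid arrays gave 39 and 18 genes although no probe of sif was raised by over 1 on any of their arrays: the highest ratio was 0.48, at 8536 to 8573 in truncated Sif replicate 1. A position effect common to all slides is argued against as the whole cause. With position in the model the called genes kept a median of 0.985 (full-length) and 0.922 (truncated) of their log2 fold change, every gene beyond 2 SE. These genes were picked in the same data, and the term cannot remove an effect of position on these 2 slides alone. Calls still ended, with 33 genes past for full-length Sif, 17 of them among the 39, and 0 for truncated Sif. The median SE rose from 0.29 to 0.31 and from 0.29 to 0.33, while the median fold went from 1.10 to 1.13 and from 1.13 to 1.04. In the slide-mates without a Sif plasmid the called genes moved in the median by 0.302 (full-length) and 0.415 (truncated) of their move in the Sif arrays. The mean over these slide-mates had the same sign as the call for 34 of 39 and 17 of 18 genes. The GFP arrays of the 2 slides thus cannot be told apart from an effect of the plasmids, because each slide holds 1 GFP array. An effect of Sif stays open and was not tested.

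Further values lay far from their group or from the controls. In Cdc42 RNAi replicate 5, Cdc42 had -0.80 (the other 4: -0.32 to -0.18), RhoL -2.42 (-0.41 to -0.14) and Moe -3.27 (-0.82 to -0.06). In Rac1 RNAi replicate 1, Rho1 had -1.76 (the other 5: -0.61 to -0.13) and pav 1.34 (0.11 to 0.46). In RhoBTB RNAi replicate 2, twy had 1.37 (the other 3: 0.11 to 0.28). On the array without a group, the RhoL probe at 406 to 440 read 12.26 in normalised log2 intensity, above the 30 GFP arrays at 9.16 to 11.2.

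Each count from groups of at least 3 arrays was set beside 100 splits of the same arrays, the real one included; the 6 comparisons of groups of 2, both Sif plasmids among them, were not. For Rho1 against Rac1 RNAi, 1 split, the real one, gave 2 genes and the highest other gave 1. These 2 genes are the targets Rho1 and Rac1, which the dsRNAs themselves set apart. The splits thus say nothing there about a response of other genes. Chance could not be excluded for the counts that follow. As many genes came from 13 splits for Rho1 RNAi (real 3, highest other 57), 5 for Rac1 (3, 11), 13 for Cdc42 (3, 210), 36 for Mtl (2, 242), 17 for CG3799 (9, 257) and 7 for average RNAi (2, 55; 40 further splits could not be fitted). They came from 9 splits for Rho1 against Cdc42 RNAi (16, 335) and 9 for Rac1 against Cdc42 RNAi (2, 91). For the counts of 0 the comparison decides nothing, since all 100 splits must be as large; the highest other was 115 for RhoBTB, 110 for RhoGAP1A, 112 for sif, 109 for pbl and 150 for RhoGAP50C and RacGAP50C. Why some splits gave many times the real count was not tested. The 3 least-agreeing arrays are a candidate for some comparisons. In the highest other split, at least 1 of them lay in the group (for average RNAi, among the GFP arrays). The exceptions were Rac1 RNAi and Rho1 against Rac1 RNAi. At least 1 lay in the group in 8 of the 11 larger splits for Cdc42 against 18 of all 99 other splits, in 16 of 30 against 19 for Mtl, in 10 of 16 against 14 for CG3799, in 16 of 31 against 23 for RhoGAP1A, in 5 of 9 against 17 for Rho1 and in 6 of 7 against 45 for Rac1 against Cdc42 RNAi. The share was lower in others: 1 of 3 against 17 for Rac1, 4 of 8 against 46 for Rho1 against Cdc42 RNAi, 4 of 21 against 8 for RhoBTB, 6 of 33 against 11 for sif, 12 of 45 against 14 for RhoGAP50C and RacGAP50C, and 2 of 30 against 2 for pbl. Among the GFP arrays it was 5 of 6 against 70 for average RNAi. What sets apart the larger splits without these arrays was not tested.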

How the results depend on the processing

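The settings with the pixel mean, no background correction, the authors' table, array quality weights, the 8 re-annotated arrays or the 3 least-agreeing arrays left out and each GFP array left out were chosen after seeing the data; the others were written down before the data were examined. Counts are of genes past adjusted p 0.05 in limma, 50C stands for the RhoGAP50C and RacGAP50C arrays together, and the name of a group stands for its comparison with GFP. Of the counts, correlations and amplicon values recomputed under the alternatives, 350 stayed the same, 182 moved and 5 reversed. A count was called the same if it equalled the reported one, or lay within 1.5-fold of it with neither at 0. Of the values for named genes, 2235 stayed the same, 348 lost the threshold, 72 gained it and 17 reversed. The lower values of Rho1 and Rac1 under their own dsRNA and the higher value of Mtl kept their sign under every setting run. Except where fewer arrays or genes entered, the cause of a move was not tested. Arrays of a slide deviated from their group means together (median r = 0.56 over 129 pairs, against -0.02 between slides), and slide is the block in the reported fit. Replicate numbers were given here in accession order and pair no arrays. Quantile normalisation over all arrays, listed as an alternative, is the reported setting because the spot files were not normalised. Leaving the RhoGEF64C arrays out of their group gives no value. The preparation ratios could not be computed for 1 comparison, and average RNAi had no array left out in turn. With the mean over all probes, the target RhoGEF4 in RhoGEF4 RNAi was 1.36. Arrays have no read depth; the spot intensity over background, with array medians from 111 to 4364.2, limits what dim probes show.

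With each array centred on its median in place of quantile normalisation, counts were 0 for Cdc42 RNAi, full-length Sif, average RNAi, Rho1 against Cdc42 and Rac1 against Cdc42, 1 for Rho1 RNAi, Rac1 RNAi, Mtl RNAi and truncated Sif, and 4 for sif RNAi. Rac2 had 0.30 with amplicon 1 and 0.42 with amplicon 2. The sign reversed for Cdc42 in Rho1 RNAi (-0.0322). With no background correction, counts were 1 for Rac1 RNAi, and 5 for Rho1 RNAi. List tests past the threshold numbered 3: Rho GTPases and cytokinesis in Cdc42 RNAi, and the actin genes with RhoF30L. With the mean of the pixels of a spot in place of the median, counts were 1 for Rac1 RNAi and pbl RNAi, 2 for 50C, 5 for sif RNAi, and 6 for Cdc42 RNAi. With the authors' deposited value table, whose scale is not stated, counts were 1 for Rho1 RNAi, RacF28L, full-length Sif, RhoGEF4 RNAi and Rac1 against Cdc42, 2 for Rho1 against Cdc42, 3 for CG3799 RNAi, 5 for truncated Sif, 7 for pbl RNAi and average RNAi, 20 for sif RNAi, 37 for RhoGAP1A RNAi, and 47 for 50C. With the dimmest 30% of genes left out, counts were 2 for sif RNAi, 5 for truncated Sif, and 17 for full-length Sif. With an intensity trend in the moderation, the count was 3 for sif RNAi. With a minimum of 1.5-fold, the count was 0 for average RNAi. With no replicate block, that is with no slide effect in the model, counts were 0 for CG3799 RNAi, truncated Sif, full-length Sif, average RNAi, Rho1 against Cdc42 and Rac1 against Cdc42, 1 for Rho1 RNAi, Rac1 RNAi, Mtl RNAi and Rho1 against Rac1, and 301 for Cdc42 RNAi against GFP. The sign reversed for dia in Rho1 RNAi (-0.22), pav in Rho1 RNAi (-0.13), Cdc42 in Rac1 RNAi (-0.10), PolE4 in Cdc42 RNAi (0.0482), RhoBTB in Mtl RNAi (-0.29), Act87E in RhoBTB RNAi (-0.19), Obp69a in pbl RNAi (-0.18), bin in RhoGEF4 RNAi (0.23), PolE4 in Rac1 against Cdc42 RNAi (-0.10) and the target Rac2 in Rac2 RNAi (0.13). With slide as a random block (correlation 0.726), counts were 0 for average RNAi, 1 for sif RNAi, 3 for CG3799 RNAi, 5 for truncated Sif, 8 for Rac1 against Cdc42, and 94 for Cdc42 RNAi. With arrays taken as independent, the count was 1 for Rac1 RNAi and average RNAi. With log2 ratios to the slide GFP and 1 value per preparation, counts were 0 for Rho1 against Cdc42, 1 for Rho1 RNAi, Rac1 RNAi, Mtl RNAi, CG3799 RNAi and 50C, 8 for Cdc42 RNAi, 12 for sif RNAi, and 31 for truncated Sif. The sign reversed for RhoGAP1A in RhoGAP1A RNAi against GFP (-0.00897). With only the compared groups and the GFP arrays of their slides in the fit, counts were 0 for Cdc42 RNAi, Mtl RNAi, CG3799 RNAi, truncated Sif, full-length Sif, average RNAi, Rho1 against Cdc42 and Rac1 against Cdc42, 1 for Rho1 RNAi, 6 for RacF28L, 10 for 50C, and 17 for Rac1 RNAi. With the mean of the other RNAi groups as the reference, counts were 0 for Rac1 RNAi, 1 for sif RNAi, and 5 for CG3799 RNAi. List tests past the threshold numbered 3: cytokinesis in Cdc42 RNAi, and Rho GTPases and the JNK pathway in Mtl RNAi. The Rho GTPase list holds Mtl itself, and this reference holds knockdowns of other members. In that list the mean was 0.37 and the median 0.09, with 4 of 7 values above 0 and 1 gene past over all genes. Its pass is thus not evidence of a shared rise. With position on the slide in the model, counts were 0 for truncated Sif and average RNAi, 1 for Rac1 RNAi, Mtl RNAi and CG3799 RNAi, and 8 for Rho1 against Cdc42. The similarity r, with the value for unchanged groups in the same design in parentheses, was 0.72 for Rho1 RNAi with Rac1 RNAi (0.53), 0.30 for Rho1 RNAi with Cdc42 RNAi (0.35), 0.25 for Rac1 RNAi with Cdc42 RNAi (0.30), 0.21 for Rho1 RNAi with pbl RNAi (0.09), 0.33 for Rho1 RNAi with RhoGAP50C and RacGAP50C (0.19), 0.50 for pbl RNAi with RhoGAP50C and RacGAP50C (0.43), 0.30 for Rho1 RNAi with RhoF30L (0.14), 0.27 for Rac1 RNAi with RacF28L (0.20), 0.29 for sif RNAi with truncated Sif (0.38), 0.66 for truncated Sif with full-length Sif (0.45) and 0.26 for truncated Sif with RacF28L (0.19). With array quality weights, counts were 0 for CG3799 RNAi and truncated Sif, 1 for RacF28L, p190RhoGAP RNAi and RhoGEF4 RNAi, 2 for full-length Sif, 3 for sif RNAi, 7 for RhoGAP1A RNAi, 9 for RhoBTB RNAi, 11 for Cdc42 RNAi, 17 for Rho1 against Rac1, 25 for Rac1 against Cdc42, 39 for average RNAi, 73 for pbl RNAi against GFP, 215 for Rac1 RNAi, and 303 for Rho1 RNAi against GFP. The sign reversed for RhoGAP1A in RhoGAP1A RNAi (-0.0475). Without the 8 re-annotated arrays, counts were 0 for Rac1 RNAi and average RNAi, 1 for Mtl RNAi, sif RNAi and 50C, 4 for CG3799 RNAi, and 8 for Rho1 against Cdc42. Without the 3 arrays that agree least with the others, counts were 0 for average RNAi and Rac1 against Cdc42, 1 for Mtl RNAi and CG3799 RNAi, 2 for Rho1 against Cdc42, 10 for sif RNAi, 37 for truncated Sif, and 71 for full-length Sif. The similarity r, again beside unchanged groups, was 0.54 for Rho1 RNAi with Rac1 RNAi (0.44), 0.41 for Rho1 RNAi with Cdc42 RNAi (0.18), 0.36 for Rac1 RNAi with Cdc42 RNAi (0.08), and the similarity: Rac1 RNAi with RacF28L plasmid was 0.0380 (0). Over only the genes past the threshold in either comparison, for which no value of unchanged groups was computed, r was 0.31 for Rho1 RNAi with Rac1 RNAi, 0.49 for Rho1 RNAi with Cdc42 RNAi, 0.30 for Rac1 RNAi with Cdc42 RNAi, 0.52 for sif RNAi with truncated Sif, 0.81 for truncated Sif with full-length Sif and -0.53 for truncated Sif with RacF28L.

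Leaving out each array of the compared groups in turn gave 2 to 3 genes for Rho1 RNAi, 0 to 3 for Rac1 RNAi, 3 to 220 for Cdc42 RNAi, 1 to 7 for Mtl RNAi, 2 to 13 for CG3799 RNAi, 0 to 20 for sif RNAi, 0 to 1 for pbl RNAi and 0 to 4 for 50C. It gave 0 to 1 for RhoF30L, 0 to 25 for truncated Sif, 0 to 107 for full-length Sif, 2 to 3 for Rho1 against Rac1, 2 to 273 for Rho1 against Cdc42 and 0 to 190 for Rac1 against Cdc42. RhoBTB, RhoGAP1A, p190RhoGAP and RhoGEF4 RNAi and RacF28L stayed at 0. Where a group was left with 1 array, that array is assumed to vary like the other groups. Leaving out each GFP array of the slides gave 2 to 4 for Rho1 RNAi, 0 to 3 for Rac1 RNAi, 0 to 86 for Cdc42 RNAi, 1 to 3 for Mtl RNAi, 0 to 37 for CG3799 RNAi, 0 to 1 for sif RNAi and 0 to 5 for 50C. It gave 0 to 30 for truncated Sif, 13 to 59 for full-length Sif, 2 for Rho1 against Rac1, 8 to 80 for Rho1 against Cdc42 and 2 to 47 for Rac1 against Cdc42, and 0 for the others. The sign reversed for RhoGAP1A in RhoGAP1A RNAi without replicate 4 (-0.0476; 0.18 without replicate 3), Exn in CG3799 RNAi without replicate 2 (-0.51; 0.45 without replicate 1) and a gene without a symbol, FBgn0019949, in RhoF30L without replicate 2 (-0.38; 2.60 without replicate 1).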

Other observations

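The tests of single arrays with their own dsRNA were not planned as comparisons, and the genes here were chosen after their values were seen. In the single RhoGEF2 RNAi array, RhoGEF2, an exchange factor of Rho1, had ratios to the GFP array of the slide from -0.89 to -0.58 over 3 probes. RhoGAP5A had -0.94 to -0.28 over 3 probes in its RNAi array, RhoGAP19D -0.74 to -0.08 over 3 probes and the exchange factor trio -0.67 to 0.08 over 3 probes, so the probes of a gene disagree here too. In 1 of its 2 RNAi arrays RhoGAP54D had -1.48 at 3188 to 3222, a probe of the second layout, and -0.68 and -0.06 at 2 other probes; in the other array 3 probes read -0.85 to -0.53. In the 1 Rac2 RNAi array with a GFP control, Rac1 had ratios of 2.46, 0.31 and 0.66 at 3 probes, the first at the probe that stands for Rac1, where this GFP array was itself low (10.64, against a median of 12.07 over the GFP arrays of the layout).

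The 1 array that entered no group is labelled for RhoL in its title and for Mtl in its source name. Its RhoL probes read 12.26 at 406 to 440, a ratio of 2.86 to the GFP array of its slide, and 7.13 at 158 to 192, a ratio of -1.75, while a probe of the second layout at 478 to 512 had a ratio of -0.15. Of the 128 other arrays, 0 lay above the first value and 128 above the second. Its Mtl probes had ratios of 0.11, -0.25 and -0.03.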
